A study of Mus musculus with 16 samples.

How the data were processed

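RNA was measured by sequencing in 16 primary explants of mouse epicardium, 8 cultured with blebbistatin and 8 without. The epicardium is the outer cell layer of the heart, and an explant is a piece of tissue set in culture so that its cells grow out. Per the labels, the explants came from C57BL6 mice, grew on a collagen gel and were annotated as epicardial cells. The dose of blebbistatin reads 20 in the labels, but its unit is written as mM in one place and as mm in another, so the concentration is not settled here. Whether the controls received the solvent of the drug is not given in the sources used here. RNA was extracted with a column kit, amplified with an Ovation RNA-Seq kit and made into libraries with a Nextera XT kit, per the labels' protocols.

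The authors deposited a table of raw read counts per gene, with a column for each explant, and this count is the unit used throughout. Per the submitters' processing notes, TopHat2 2.1.0, Bowtie2 2.2.6.0, SAMtools 1.3, HTSeq 0.6.1p1 and edgeR were used with mouse build mm10 (GRCm38). The role of each tool, the annotation release, the strand setting of the counting and any filter are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping gene on the other strand may have been counted together. The deposited counts had been filtered before deposit, as tested on the table itself: each of its 15805 genes exceeded 1 CPM (the usual scaling of counts to a fixed library total) in at least 4 of the 16 libraries, and 447 did so in exactly 4. Genes below that level were not analysed here. A spreadsheet had turned 21 gene names in the table into dates and 72 names were blank, so symbols were restored from the Ensembl identifiers, of which 15665 matched the reference. Gene positions are those of GENCODE M21 on build GRCm38.

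Total counts per library ran from 20176386 to 89620195, so that 1 CPM stood for about 20.2 counts in the shallowest library. The genes mt-Rnr1 and mt-Rnr2, the ribosomal RNAs of mitochondria, held on average 16.8% of the counts. Within a group no library repeated another: the closest pair, control 7 and control 8, differed by a chi-square of 49.4 per degree of freedom, far above sampling noise.

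Counts were scaled by edgeR's TMM method and filtered with filterByExpr, which left 15675 genes and took out 130. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit, group as the only term), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2 scale, blebbistatin minus control, with their standard errors. Levels are TMM-scaled CPM, as mean ± SD over 8 libraries, and log2 CPM used a prior count of 2. The biological coefficient of variation was 50.1%.

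A total of 35 gene lists were fixed by name. Those with at least 5 tested members, 33 of them, were tested with camera (limma 3.58.1) at its preset correlation of 0.01 between genes, and again with a correlation estimated from the data. Camera sets a list against the other genes, and fry, also run, sets it against no change. Members were also counted with p-values adjusted over the list alone. The mean log2 CPM of each list per library was compared between groups by a 2-sided exact permutation test over all 12870 splits of 16 libraries into 8 and 8. This test per library was added after the results of camera had been seen. The same exact test, adjusted over 13 measures, served for total counts, genes detected, mitochondrial share and the summed CPM of marker lists of other cell types, where CPM was relative to the library's total counts without TMM scaling.

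The genes named in the text follow a rule fixed before the data were examined, as were the groups, tests, gene lists and most alternatives. It took 17 genes of myosin II, epicardium, epithelial-mesenchymal transition, contraction and proliferation whatever their result. It further took the 8 higher and 8 lower genes of smallest p among those called that reached 5 CPM in the higher group and lay on the test's side of the other group's median in at least 7 of 8 libraries, leaving out predicted and small RNA genes, and up to 4 members of smallest p of each list described. Of these, Cdh1 was not analysed here. Genes outside the rule are named only where the text says so. Ctgf and Cyr61 appear under their current symbols Ccn2 and Ccn1.

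On counts simulated from these libraries' means and depths over 15597 genes, with 200 genes and a list changed, the main test recovered 43 of 100 genes changed 2-fold and 74 of 100 changed 4-fold, and 3.25% of its calls were unchanged genes. Of the gene lists, camera called the single list that had been shifted and no other, with either correlation. The simulated genes were drawn independently of each other, whereas the estimated correlation was, for example, 0.294 in the list of SRF targets. The simulation thus does not show how often camera calls unchanged lists of correlated genes. On the same simulated counts 14.8% of the calls of DESeq2 and 2.65% of those of limma voom were unchanged genes. Each simulated gene had the spread that edgeR had estimated for it, which may favour edgeR.

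Alternatives were other scalings (the size factors of DESeq2, upper quartile), no filter or a filter of 1 CPM in 8 libraries, a replicate block, limma voom with sample weights, DESeq2 1.42.0, a threshold of 0.01, covariates for the share of the 10 most abundant genes and for genes detected, and leaving out each library in turn. Alternatives added after seeing the data were covariates for the level of Y-linked genes and of macrophage markers, and removal of mitochondrial and abundant noncoding rows. Added then as well was leaving out blebbistatin 1 and 8, the libraries with the fewest genes detected. The labels do not say whether the explants came from separate embryos, so the p-values measure only the spread between these samples, which may be partly technical. Library measures and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.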

Results

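The transcriptomes of 16 cultured explants of mouse epicardium were compared, 8 treated with blebbistatin and 8 controls without it. Blebbistatin is a small molecule that blocks the ATPase of myosin II, the motor protein with which cells pull on their actin filaments, and per the labels it was added to inhibit nonmuscle myosin II. Total counts were 20176386 to 89620195 in the blebbistatin libraries and 27065611 to 60321622 in the controls.

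The targets of the drug were examined first, by the level of the genes for the 3 nonmuscle myosin II heavy chains. By edgeR 0 of 3 passed, with 1 at an unadjusted p under 0.05, while DESeq2 called 1 lower and limma voom 0. Myh9, which encodes the heavy chain of myosin IIA (chromosome 15, 77760587 to 77842175), stood at 390 ± 112 CPM with blebbistatin and 571 ± 80.5 CPM in controls (SD, n = 8 each), a log2 fold change of −0.55 (SE 0.15, adjusted p = 0.101). Myh10, for the heavy chain of myosin IIB (chromosome 11, 68691559 to 68816632), stood at 801 ± 129 and 919 ± 119 CPM, a log2 fold change of −0.20 (SE 0.11, adjusted p = 0.516). Myh14, for myosin IIC, was low at 3.21 ± 2.87 and 2.40 ± 1.72 CPM (adjusted p = 0.786). Myh9 passed the threshold without blebbistatin 5 (adjusted p = 0.0266) and with DESeq2 (adjusted p = 0.0232), and its adjusted p ran from 0.0232 to 0.310 over all alternatives.

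Among 16 tested subunits and regulators of myosin II, 1 rose, 0 fell and 15 did not pass the edgeR test. DESeq2 called 1 higher and 1 lower and limma voom 1 higher. The gene that rose was Mylk, which encodes myosin light chain kinase, an enzyme that activates myosin II (chromosome 16, 34745210 to 35002420). Its level was 429 ± 184 CPM with blebbistatin and 131 ± 66.7 CPM in controls, a log2 fold change of 1.72 (SE 0.30, adjusted p = 0.00956), and all 8 treated libraries lay above the control median. Adjusted over the list alone, Mylk rose and Myh9 and Myl12a fell. Against the other genes the list was lower in camera (median log2 fold change −0.21, adjusted p = 0.0322), a call lost with the estimated correlation (adjusted p = 0.179 with an estimated correlation) and, at 0.0551 to 0.0728, without blebbistatin 3, 6 or 7 or control 4, 5 or 6. Mprip, for a scaffold of myosin phosphatase, had a log2 fold change of −0.28 (adjusted p = 0.337).

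**Figure D1:**
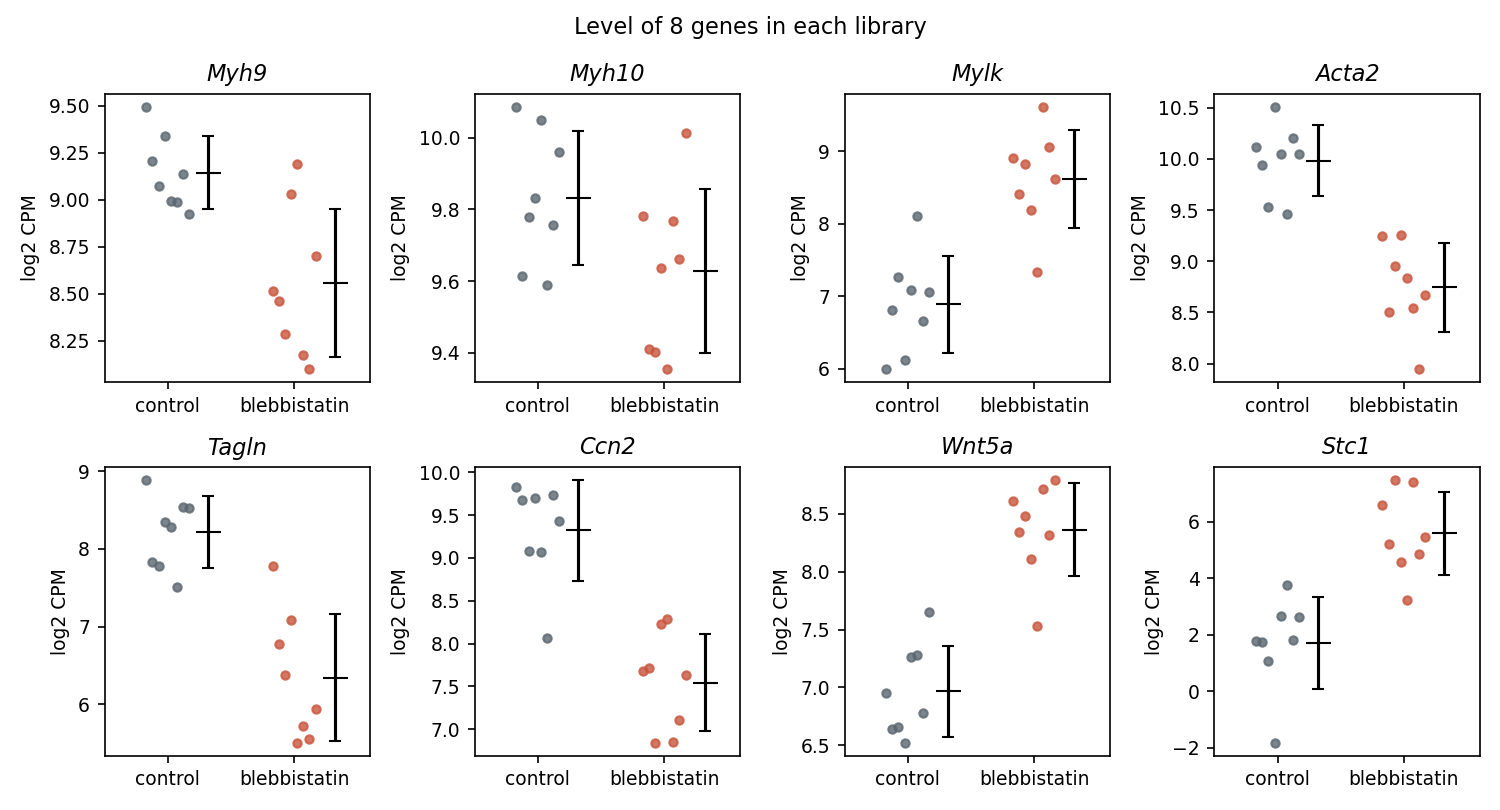
Log2 CPM of Myh9, Myh10, Mylk, Acta2, Tagln, Ccn2, Wnt5a and Stc1 in each library, controls on the left and blebbistatin on the right of each panel. Points are libraries, and the bar beside them is the mean ± SD of 8. Each vertical axis is log2 and has its own range. All 8 blebbistatin libraries lie above the control median for Mylk, Wnt5a and Stc1 and below it for Acta2, Tagln and Ccn2, and the groups overlap in each panel but that of Acta2.

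Across the transcriptome, the matrix protein gene Ccn2 and the actin gene Acta2 were among those that fell most clearly with blebbistatin, and the genes of the secreted proteins Wnt5a and Stc1 among those that rose. Ccn2, a secreted protein of the matrix also known as connective tissue growth factor (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683), fell from 681 ± 218 to 199 ± 76.9 CPM, a log2 fold change of −1.77 (SE 0.25, adjusted p = 0.00283). Acta2, the actin of smooth muscle (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), fell from 1037 ± 241 to 445 ± 125 CPM (−1.22, SE 0.18, adjusted p = 0.00411). Wnt5a, a secreted Wnt ligand (ENSMUSG00000021994, chromosome 14, 28504750 to 28527448), rose from 129 ± 37.5 to 339 ± 83.1 CPM (1.39, SE 0.18, adjusted p = 0.00233). Stc1, a secreted glycoprotein (ENSMUSG00000014813, chromosome 14, 69029238 to 69041804), rose most among the named genes, from 4.80 ± 4.03 to 73.0 ± 66.7 CPM (3.92, SE 0.65, adjusted p = 0.00701).

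In all, edgeR called 95 of 15675 genes at an adjusted p under 0.05, 40 higher and 55 lower with blebbistatin, of which 25 and 28 changed at least 2-fold. At an unadjusted p under 0.05 there were 1911, and the median log2 fold change of all tested genes was 0.04. Besides Ccn2 and Acta2, the lower genes of smallest p were the axon guidance ligand Slit2 (log2 fold change −1.16), the fibril-associated collagen Col12a1 (−1.53), the adhesion molecule Mcam (−1.63), the receptor tyrosine phosphatase Ptprz1 (−1.67), the magnesium transporter Cnnm4 (−1.43) and the LIM-domain protein Fhl1 (−1.70). Their adjusted p-values ran up to 0.00679, and each was below the control median in 8 of 8 treated libraries. Besides Wnt5a and Stc1, the higher genes of smallest p were Clca3a1 (log2 fold change 1.16), the cytokine receptor Lifr (1.07), the filopodial motor Myo10 (0.88), the potassium channel Kcnb2 (1.52), Clca3a2 (1.19) and the mitochondrial thiolase Acaa2 (1.03), all with adjusted p-values up to 0.00701 and above the control median in 8 of 8 treated libraries. Clca3a1 (chromosome 3, 144729677 to 144760977) and Clca3a2 (144796559 to 144819494) are neighbouring paralogs, so reads may be split between them and their separate values are uncertain. Reads may also be shared where genes overlap, as Wnt5a does with Gm2670, Mcam with Gm10687, Kcnb2 with Gm37138 and Tagln with Pcsk7.

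Of the genes named in advance, Tagln, an actin-binding protein of smooth muscle, fell from 310 ± 96.5 to 94.4 ± 60.0 CPM (log2 fold change −1.72, SE 0.30, adjusted p = 0.0112). Ccn1, another secreted matrix protein, fell from 648 ± 144 to 357 ± 70.9 CPM (−0.86, SE 0.16, adjusted p = 0.0135). The transcription factor genes that mark the epicardium did not pass edgeR: Tbx18 had a log2 fold change of −0.68 (adjusted p = 0.0794), Wt1 of −0.21 (adjusted p = 0.632) and Tcf21 of 0.14 (adjusted p = 0.773), and Aldh1a2, for an enzyme of retinoic acid synthesis, one of −0.15 (adjusted p = 0.734). Tbx18 passed with DESeq2 (adjusted p = 0.0136), with the macrophage covariate (adjusted p = 0.03) and without control 6 (adjusted p = 0.023), and its adjusted p ran from 0.0136 to 0.28 over all alternatives. By edgeR neither Snai1 (0.36, adjusted p = 0.724) nor Snai2 (0.05, adjusted p = 0.973), transcription factors of the epithelial-mesenchymal transition, nor Ankrd1 (−0.94, adjusted p = 0.357) passed. Mki67, a marker of dividing cells, stood at 258 ± 78.1 CPM with blebbistatin and 169 ± 41.2 CPM in controls (0.61, adjusted p = 0.159), and Cdkn1a, an inhibitor of the cell cycle, at 322 ± 162 and 390 ± 114 CPM (−0.28, adjusted p = 0.736).

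The sexes of the explants were uneven. The Y-linked gene Ddx3y exceeded 10 CPM in 5 of 8 blebbistatin libraries and 2 of 8 controls (2-sided Fisher's exact test, p = 0.315), and control 5 held Ddx3y at 56.2 CPM together with 342 CPM of Xist, the RNA of the inactive X chromosome. With the level of Y-linked genes as a covariate, edgeR called 21 genes, all among the 95, and the calls of Stc1, Acaa2 and Ccn1 ended (adjusted p = 0.136, 0.0564 and 0.0584). Their log2 fold changes were then 3.05, 0.94 and −0.86. Without blebbistatin 1 and 8, which had the fewest genes detected (15468 and 15492), there were 65 calls, 45 of them among the 95.

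The number of calls rested on single libraries: it was 180 without blebbistatin 5, 49 without blebbistatin 6, 62 without blebbistatin 8, 60 without control 1, 58 without control 2, 52 without control 4, 206 without control 6, 44 without control 7 and 54 without control 8. It was 424 with DESeq2, 245 with limma voom, 227 with a macrophage covariate and 44 with a covariate for the 10 most abundant genes, where Stc1 had an adjusted p of 0.0516. As each library was left out in turn, the highest adjusted p in edgeR was 0.00996 for Ccn2 and Wnt5a, 0.0122 for Acta2 and 0.0273 for Stc1. For Tagln it was 0.0368 and for Ccn1 0.038. Wnt5a and Stc1 were named for their small p, and these values do not cover the other calls.

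Gene lists asked which groups of genes moved together. Among those that did were genes of smooth muscle and contraction, of which 20 were tested: by edgeR 6 fell, 1 rose and 13 did not pass. By DESeq2 9 fell and 2 rose, and by limma voom 8 fell and 1 rose. Acta2, Tagln and Actn1, which encodes a crosslinker of actin filaments (log2 fold change −0.88, adjusted p = 0.0198), were among those that fell, and Mylk was the gene that rose. Adjusted over the list alone, 11 fell and 2 rose, Mylk among them. The median member had a log2 fold change of −0.84. The list was lower than the other genes in camera (adjusted p = 7.89e-12) and with the estimated correlation (adjusted p = 0.0177). Its mean log2 CPM was 5.19 ± 0.32 with blebbistatin and 5.89 ± 0.25 in controls, and all 8 treated libraries lay below the control mean (exact permutation test, p = 0.000311, adjusted over 33 lists 0.00769).

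Target genes of serum response factor (SRF) and its actin-sensing cofactors of the MRTF family were lower as well. Of 32 tested, 6 fell, 0 rose and 26 did not pass by edgeR, with 20 at an unadjusted p under 0.05. DESeq2 called 13 lower and 1 higher and limma voom 12 lower. With adjustment over the list alone 15 fell and 1 rose. Ccn2, Acta2, Fhl1 and Tagln led the list, with a median log2 fold change of −0.50 over all members (adjusted p = 2.42e-22 in camera and 0.0298 with an estimated correlation). Target genes of YAP and TAZ, cofactors that respond to tension in the cytoskeleton, had a median of −0.41: of 26 tested, 3 fell, 0 rose and 23 did not pass by edgeR, with 11 at an unadjusted p under 0.05. DESeq2 called 6 lower and limma voom 4, and 8 fell adjusted over the list alone. The 3 that edgeR called were Ccn2, Ccn1 and Amotl1, which encodes a binding partner of YAP (−0.83, adjusted p = 0.0235). The YAP list passed in camera (adjusted p = 1.82e-09) and with the estimated correlation (adjusted p = 0.0484). The mean log2 CPM of the SRF list was lower by exact permutation test (p = 0.000466, adjusted 0.00769), as was that of the YAP list (p = 0.0042, adjusted 0.0282), each below the control mean in 8 of 8 treated libraries.

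Collagens of the matrix and the enzymes that modify and crosslink them were lower. Of 26 tested, 5 fell, 0 rose and 21 did not pass by edgeR, with 11 at an unadjusted p under 0.05. DESeq2 called 7 lower and limma voom 6, and 8 fell adjusted over the list alone. Lox, the enzyme that crosslinks collagen, fell from 1924 to 745 CPM (log2 fold change −1.37, SE 0.27, adjusted p = 0.0198), Col8a1 from 1983 to 844 CPM (−1.23, SE 0.24, adjusted p = 0.0198) and Col5a1 from 502 to 291 CPM (−0.79, SE 0.14, adjusted p = 0.011). The list had a median of −0.31 and passed in camera (adjusted p = 3.1e-08) and with the estimated correlation (adjusted p = 0.0177). Its mean log2 CPM was lower in 8 of 8 treated libraries than the control mean (exact permutation test, p = 0.00435, adjusted 0.0282).

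**Figure D2:**
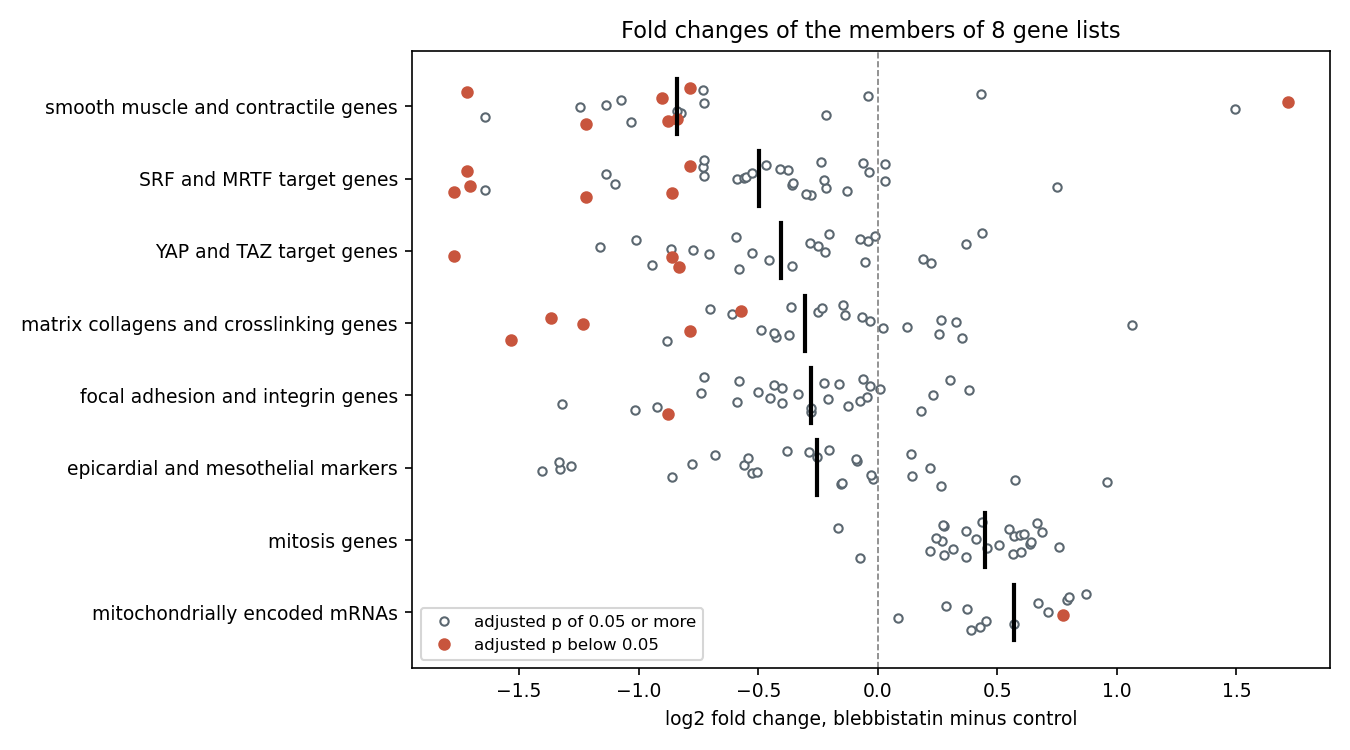
Log2 fold change (blebbistatin minus control) of each tested member of 8 gene lists, a point per gene, filled where the adjusted p over all genes was below 0.05. The black line is the list's median. Most contractile, SRF, YAP and collagen genes lie left of 0, with medians of −0.84, −0.50, −0.41 and −0.31, and most mitosis genes lie right of it with none filled.

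Genes of focal adhesions and integrins, which tie the cytoskeleton to the matrix, had a median of −0.28: of 29 tested, 1 fell (Actn1) and 28 did not pass by edgeR. DESeq2 called 6 lower and 1 higher and limma voom 6 lower, and 10 fell and 2 rose adjusted over the list alone. Their call in camera (adjusted p = 2.21e-07) was lost with the estimated correlation (adjusted p = 0.126 with an estimated correlation), and the mean per library was lower (exact permutation test, p = 0.00326, adjusted 0.0282). Of 24 mesenchymal and fibroblast genes, 2 fell (Col5a1 and Lox), 0 rose and 22 did not pass by edgeR, with 11 at an unadjusted p under 0.05. DESeq2 and limma voom each called 3 lower and 1 higher. With adjustment over the list alone 3 fell and 3 rose. Fn1, for fibronectin, had a log2 fold change of −0.56 (adjusted p = 0.0526) and Pdgfra, a growth factor receptor of fibroblasts, one of 0.82 (adjusted p = 0.0555). That list was lower in camera (adjusted p = 0.00889) but not with the estimated correlation (adjusted p = 0.167 with an estimated correlation), and lower per library (exact permutation test, p = 0.00513, adjusted 0.0282).

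Of 27 epicardial and mesothelial markers, 0 passed edgeR over all genes and 8 had an unadjusted p under 0.05, while DESeq2 called 1 higher and 3 lower and limma voom 2 lower. Adjusted over the list alone 1 rose, Bnc2 (log2 fold change 0.96, adjusted over all genes 0.0593), and 3 fell, Krt19 (−1.33), Tbx18 and Krt18 (−1.41). The list was lower in camera (median −0.25, adjusted p = 0.00038), a call lost with the estimated correlation (adjusted p = 0.294 with an estimated correlation), and its mean per library did not pass (exact permutation test, p = 0.0549, adjusted 0.121). Of 19 genes of epithelial junctions and polarity 0 passed edgeR by either adjustment and 3 had an unadjusted p under 0.05, with 1 call by DESeq2 and 0 by limma voom. Cldn3, for a protein of tight junctions, had a log2 fold change of −1.81 (adjusted p = 0.157). The list was lower in camera (adjusted p = 0.00319), but not with the estimated correlation (adjusted p = 0.261 with an estimated correlation). Of 9 transcription factors of the epithelial-mesenchymal transition 0 passed edgeR, DESeq2, limma voom or an unadjusted p under 0.05, nor did the list pass (median 0.12, camera adjusted p = 0.612), with a log2 fold change of 0.27 for Zeb1 (adjusted p = 0.421).

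Mitosis genes tended the other way. Of 26, 24 had a positive log2 fold change, 9 had an unadjusted p under 0.05 and 0 passed edgeR over all genes, with 1 call by DESeq2 and 0 by limma voom, while 3 rose adjusted over the list alone, namely Cdca8 (0.76), Mki67 (0.61) and Bub1b (0.56). The list was higher in camera (median 0.45, adjusted p = 6.53e-08), a call lost with the estimated correlation (adjusted p = 0.247 with an estimated correlation). Its mean log2 CPM was 4.58 ± 0.38 with blebbistatin and 4.13 ± 0.46 in controls, and this difference did not pass (exact permutation test, p = 0.0528, adjusted 0.121). Of 22 genes of cytokinesis, the last step of cell division, which needs myosin II, 0 passed edgeR or limma voom, 1 passed DESeq2 and 5 an unadjusted p under 0.05 (camera adjusted p = 0.106). That list passed in camera, higher, without blebbistatin 7 (adjusted p = 0.0267), control 1 (0.0225) or control 7 (0.0363), with a range of 0.0225 to 0.858 over all alternatives. Of 24 S phase genes 0 passed with any of the 3 tools and 1 an unadjusted p under 0.05 (camera adjusted p = 0.17, 0.0435 without blebbistatin 7 and 0.0435 to 0.858 over all alternatives).

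**Figure D3:**
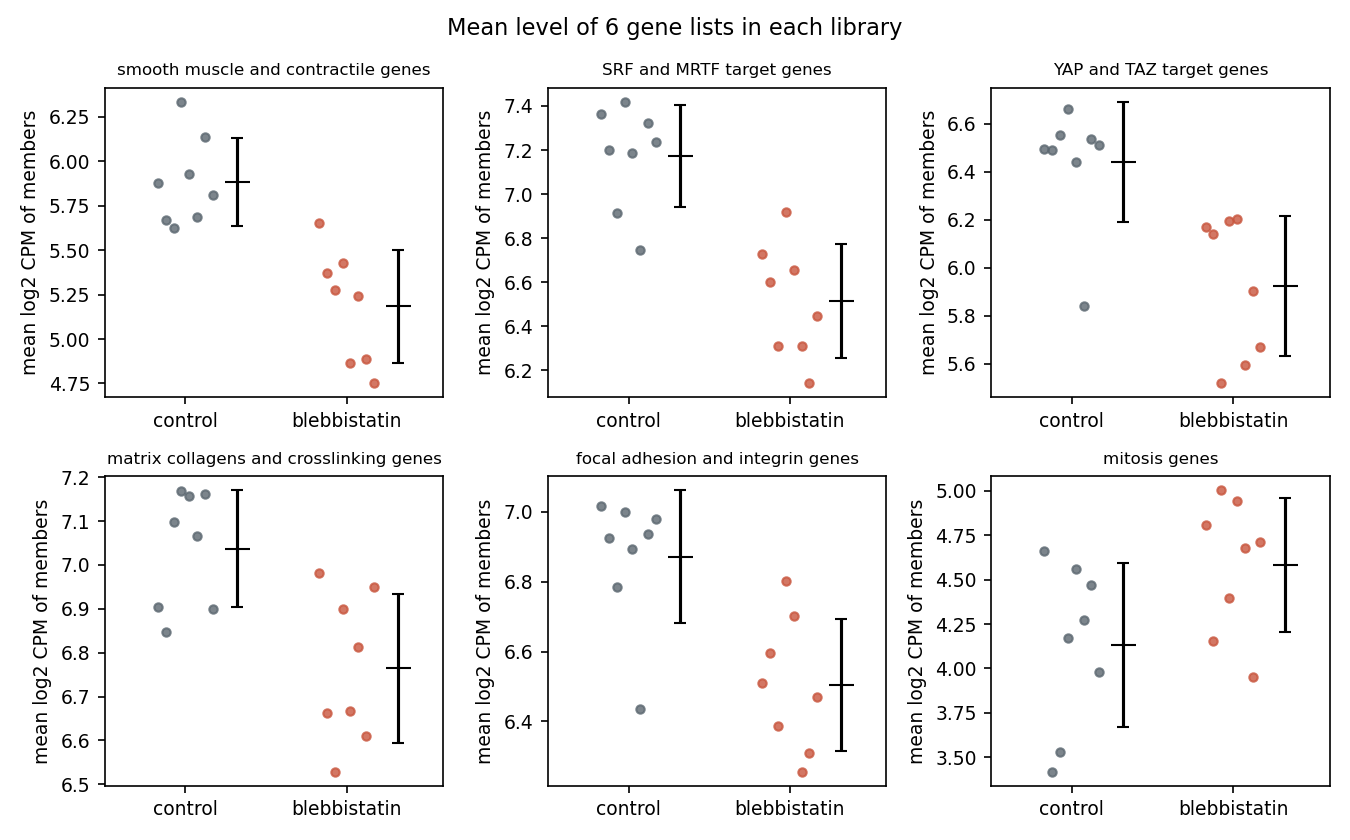
Mean log2 CPM of the members of 6 gene lists in each library, controls on the left and blebbistatin on the right. Points are libraries, and the bar beside them is the mean ± SD of 8. Each vertical axis has its own range. All 8 blebbistatin libraries lie below the control mean for the contractile, SRF, YAP, collagen and focal adhesion lists, and 7 of 8 lie above it for the mitosis list.

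Camera called 19 of 33 lists in all, 3 higher and 16 lower, and 4 calls held with the estimated correlation: the contractile, SRF, YAP and collagen lists. The estimated correlation was used on all 16 libraries only, so whether single libraries carry these 4 calls was not tested. In fry, which tests a list against no change and not against the other genes, 7 of the 19 passed, these 4 and the myosin II, mesenchymal and focal adhesion lists. By the exact permutation test per library 7 lists passed, all lower.

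The libraries of the groups also differed in what they held besides these lists. Mitochondrial genes took 21.4 ± 3.21% of the counts with blebbistatin and 16.4 ± 1.70% in controls (exact permutation test, p = 0.00326, adjusted over 13 measures 0.0215). Most of this share was ribosomal RNA, as mt-Rnr1 and mt-Rnr2 held on average 16.8% of the counts over all libraries. The 13 mRNAs encoded by mitochondrial DNA summed to 24838 ± 6096 CPM and 16552 ± 2811 CPM (exact permutation test, p = 0.00357, adjusted 0.0215). Of these 13, mt-Cytb rose by edgeR (log2 fold change 0.77, adjusted p = 0.041) and 12 did not pass. DESeq2 called 7 higher and limma voom 1 higher. Adjusted over the list alone 7 rose, mt-Nd5 (0.80), mt-Nd1 (0.71) and mt-Nd4 (0.67) among them. Camera called the list higher (adjusted p = 1.15e-09), but not with the estimated correlation (adjusted p = 0.179 with an estimated correlation). Its mean log2 CPM per library did not pass (difference 0.527, exact permutation test, p = 0.0225, adjusted over 33 lists 0.0825).

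Markers of cardiomyocytes, the muscle cells beneath the epicardium, summed to 1207 ± 139 CPM with blebbistatin and 858 ± 245 CPM in controls (exact permutation test, p = 0.00497, adjusted 0.0215). Of 11 tested, Ttn, for the giant sarcomere protein titin, rose from 15.5 to 48.2 CPM (log2 fold change 1.64, adjusted p = 0.0464) and 10 did not pass. Adjusted over the list alone, Ttn, Ryr2 (2.12) and Tnnt2 (0.66) rose and Nppb (−2.94) fell, while over all genes DESeq2 called 3 higher and limma voom 2 higher and 1 lower. As a list they did not pass in camera (adjusted p = 0.069). Settings in which they passed, higher, included the 1 CPM filter (adjusted p = 0.00395), the covariate for genes detected (0.0484) and the fits without blebbistatin 7 (0.0467) or control 6 (0.0312), and the range was 0.00395 to 0.208 over all alternatives. In fry, against no change, the list had an adjusted p of 0.0459. The summed CPM gives most weight to the most abundant markers and may rest on few genes. Hspb7, the most abundant of the 8 tested markers besides Ttn, Ryr2 and Tnnt2, had a log2 CPM of 7.083 with blebbistatin and 6.995 in controls. The higher sum thus need not be a rise of the markers as a set. The mean log2 CPM of the list per library, in which each tested marker weighs alike, did not pass (difference 0.197, exact permutation test, p = 0.22, adjusted 0.363). Transcripts of macrophages and other leukocytes differed far more within the groups than between them, at 320 to 4295 CPM with blebbistatin and 347 to 4918 CPM in controls (exact permutation test, p = 0.889). Of 15 such genes 0 passed with any of the 3 tools or at an unadjusted p under 0.05, and the list did not pass in camera (adjusted p = 0.679), with a log2 fold change of 0.70 for Cd68 (adjusted p = 0.576).

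**Figure D4:**
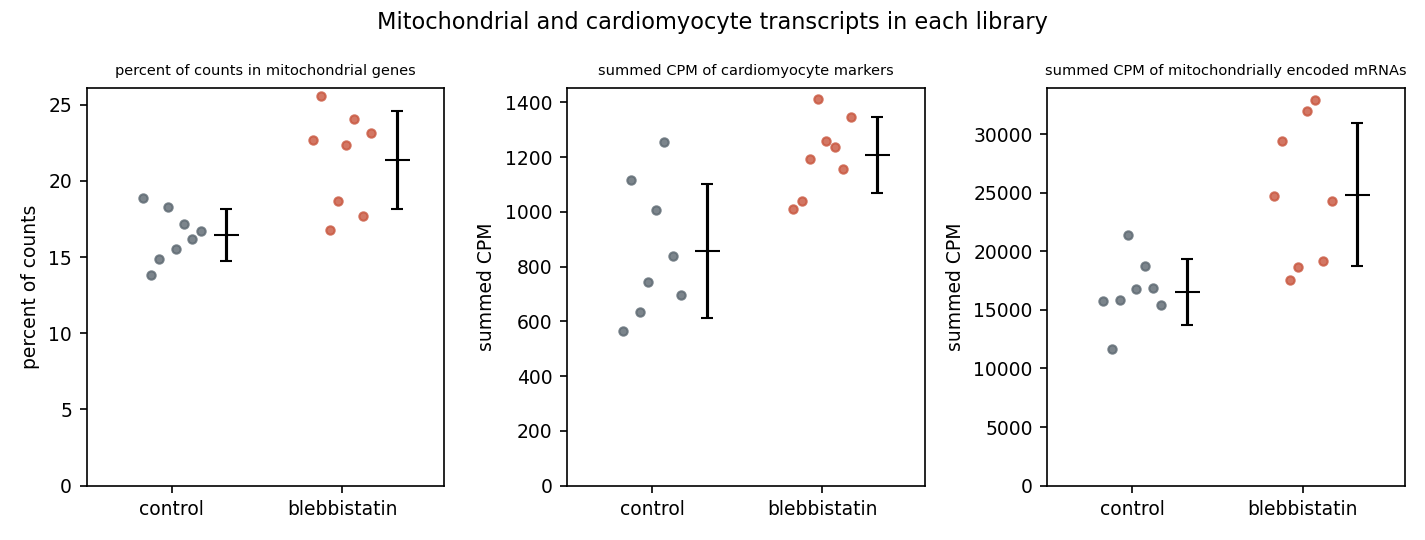
Percent of counts in mitochondrial genes, summed CPM of cardiomyocyte markers and summed CPM of mitochondrially encoded mRNAs in each library, controls on the left and blebbistatin on the right, with axes from 0. Points are libraries, and the bar beside them is the mean ± SD of 8. The means are 21.4 and 16.4%, 1207 and 858 CPM, and 24838 and 16552 CPM, higher with blebbistatin each time.

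Total counts (exact permutation test, p = 0.596), genes detected (p = 0.621), the share of the 10 most abundant genes (p = 0.167) and the summed CPM of markers of endothelium (p = 0.988), nerve (p = 0.446), pericytes (p = 0.21) and ribosomal proteins (p = 0.23) did not pass. Liver markers, at 21.8 ± 10.8 and 10.8 ± 3.58 CPM, had p = 0.018 (adjusted 0.0586), and erythroid markers, at 44.6 ± 15.5 and 78.0 ± 33.4 CPM, p = 0.0524 (adjusted 0.136) in the same exact test. Leaving out single libraries, liver markers passed without blebbistatin 4 (adjusted p = 0.049) or 5 (0.0202), in a range of 0.0202 to 0.122, erythroid markers without control 1 (0.0273, range 0.0273 to 0.268) and ribosomal proteins, lower, without blebbistatin 7 (0.0414, range 0.0414 to 0.673).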

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

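The test of cardiomyocyte markers, the covariates for Y-linked genes and macrophage markers, and the comparison with shuffled covariates were chosen after the data had been seen.

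Some libraries stood apart from the other 7 of their group, by Dixon's test of the gap to the nearest library over the range of the group. Of 86 groups of 8 libraries tested 8 did so, where chance gives about 1 in 20. Control 6 was low in Ccn2 (log2 CPM 8.06, others 9.07 to 9.83) and in Fhl1 (6.25, others 7.15 to 7.94). Blebbistatin 4 was high in Col12a1 (6.47, others 5.06 to 5.64), and blebbistatin 5 low in Ptprz1 (3.45, others 4.57 to 5.46). The 10 most abundant genes took 36.5% of the counts in control 1, against 26.4 to 29.7% in the others. The log2 summed CPM of erythroid markers was 4.17 in blebbistatin 1, against 5.23 to 6.13. That of ribosomal protein genes was 12.2 in blebbistatin 7, against 11.6 to 11.8, and 12.3 in control 2, against 11.7 to 11.9.

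The count of called genes was set against 99 other splits of the 16 libraries into 8 and 8. The real split called 95 genes and the highest other 21, so 1 of 100 splits, the real one, called as many. This argues against chance as the source of the count, though no finer than 1 in 100. Such splits cannot tell the treatment from a day or litter that went with it. For gene lists in camera the real split called 19 and the highest other 18, with a median of 7, so again 1 of 100 called as many. Splits that mix the treatments thus often called many lists at the preset correlation, and such a call alone says little.

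The joint fall of contractile, SRF and YAP genes was weighed against the uneven sex of the explants, RNA of macrophages and the higher mitochondrial share. Over the 69 members of the 3 lists the mean log2 CPM differed by −0.54 (SE 0.105). It differed by −0.553 (SE 0.118) with the Y-linked level in the model and by −0.64 (SE 0.152) with the mitochondrial share. Both lie more than 2 SE beyond a bound of −0.271, which a rule written beforehand takes from the difference without a covariate. This argues against sex and the mitochondrial share as the whole cause. With the macrophage level the mean differed by −0.544 (SE 0.0849). That level was alike in the groups (mean log2 CPM 4.36 ± 1.5 with blebbistatin and 4.38 ± 1.14 in controls). Its fit could thus hardly move the difference. Dilution would need more macrophage RNA with blebbistatin, so the equal level itself argues against it for these genes, as far as the markers measure it. An effect of the treatment stays open as a hypothesis, and effects of GC content and gene length were not tested. A candidate explanation is the block of myosin II for which the drug was added, per the labels. It was not tested apart from the difference between the groups.

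The tendency of mitosis genes to be higher was weighed against sex and dividing macrophages. Their mean log2 CPM differed by 0.448 (SE 0.211) without a covariate, by 0.343 (SE 0.226) with the Y-linked level and by 0.448 (SE 0.218) with the macrophage level. Neither value lies clear of the bound of 0.224 by 2 SE, nor does the difference without a covariate, so this test could not decide. The macrophage level was also alike in the groups (mean log2 CPM 4.36 and 4.38), so its covariate could hardly move the difference. The equal level argues against more macrophage RNA as the source, while how often macrophages divided was not tested. Sex cannot be told apart from an effect of the treatment, because the spread between libraries is too wide.

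More cardiomyocyte RNA was weighed as a possible explanation of the higher levels of Ttn, Ryr2 and Tnnt2, whose mean log2 CPM differed by 1.41 (SE 0.336). The 8 other cardiomyocyte markers tested differed by −0.258 (SE 0.181), or 0.21 (SE 0.173) without Nppb. The 3 genes were picked because they rose, which by itself leaves a lower value to the others, so this comparison decides nothing. Among the others Actn2 had a log2 fold change of 0.71 (SE 0.36), Hspb7 one of 0.17 (SE 0.25, 150 and 133 CPM), Tnni1 one of 0.08 (SE 0.25) and Myl7 one of −0.26 (SE 0.27, 77.9 and 93.4 CPM). The higher summed CPM of all markers includes the 3 genes and adds no separate evidence. More cardiomyocyte RNA and a change of these genes within the cells present therefore cannot be told apart here.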

How the results depend on the processing

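The covariates for Y-linked genes and macrophage markers, the removal of mitochondrial and abundant noncoding rows and the fit without blebbistatin 1 and 8 were chosen after seeing the data. Of 2129 values under the alternatives, 1968 kept their direction and side of the threshold (or, for counts of calls, stayed within 1.5 times), 59 no longer passed, 35 newly passed, 49 reversed and 18 counts moved further. The main count of 95 genes became 177 with the replicate block (77 of the 95 kept), 245 with limma voom (88 kept), 424 with DESeq2 (94 kept), 44 with the covariate for the 10 most abundant genes (41 kept), 22 at an adjusted p under 0.01, 21 with the Y-linked covariate (21 kept) and 227 with the macrophage covariate (95 kept). Leaving out each library in turn gave 44 to 206. Other scalings and filters gave 94 to 123. The threshold of 0.01 admits fewer genes by construction, and for the others the cause was not tested. On simulated counts 14.8% of the calls of DESeq2, 3.25% of those of edgeR and 2.65% of those of limma voom were false. Those counts had the spread that edgeR had estimated, so they do not show which further calls on the real counts were false. With the Y-linked covariate all 95 kept their direction, the median ratio of fold changes was 0.963 and that of SEs 1.1. Of 30 shuffled covariates the median gave 41 calls, from 17 to 128, and 5 gave 21 or fewer. The labels give the replicate numbers no shared animal or day. Same-numbered libraries correlated by 0.00394 to 0.279, 4 of 8 pairs over 0.1, and 5 of 16 libraries correlated best with their own number. A shared day or litter is thus neither shown nor ruled out. In the pairs numbered 1, 2, 3, 4, 6 and 8 only 1 library exceeded 10 CPM of Ddx3y, as with 63.6 CPM in blebbistatin 1 and 0.369 in control 1. This argues against a shared animal in those pairs. With the block the TGF-beta and cardiomyocyte lists passed as well (adjusted p = 0.0384 and 0.0288).

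Of 19 lists called by camera 4 passed with the estimated correlation and 7 in fry, a test against no change that called 8 in all. In the other settings, all at the preset correlation, camera called 16 to 21 lists. Myh9 passed with DESeq2 (log2 fold change −0.56), and lay at −0.66 to −0.49 as each library was left out. Reversals were limited to results that did not pass. Snai2 was at −0.14 with the replicate block, −0.12 with limma voom, −0.14 with the Y-linked covariate and −0.19 to 0.17 leaving out each library. Tcf21 was at −0.049 with the covariate for the 10 most abundant genes, and Myh14 at −0.10 with that for genes detected and −0.50 without blebbistatin 1 and 8. Camera's direction turned for cholesterol genes with the 1 CPM filter (median log2 fold change 0.029) and with the covariate for genes detected (0.0047), for endothelial markers with limma voom (0.068) and without blebbistatin 1 and 8 (0.018), and for macrophage markers with the covariates for the 10 most abundant genes (0.27) and Y-linked genes (−0.49). As each library was left out, list medians ran from −0.069 to 0.056 for cholesterol, −0.24 to 0.82 for macrophage and −0.33 to 0.038 for neural genes. Differences between groups then ran from −0.012 to 0.30 for log2 total counts, −39.4 to 5.70 for genes detected, and on the log2 scale −0.16 to 0.12 for summed endothelial and −0.40 to 0.24 for summed macrophage markers. For these the cause was not tested. Depth limits genes near 1 CPM, which is about 20.2 counts in the shallowest library.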

Other observations

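The genes of the first paragraph outside the lists were chosen after their values were seen, as was the test of unique list members.

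Some other called genes belonged to none of the lists. Steap4, a metal reductase, rose from 7.19 to 39.3 CPM (log2 fold change 2.44, adjusted p = 0.0198) and Alcam, a cell adhesion molecule, from 209 to 509 CPM (1.28, adjusted p = 0.0392). Lef1, a transcription factor of canonical Wnt signalling, rose from 4.91 to 13.4 CPM (1.45, adjusted p = 0.0198) and Fzd1, a Wnt receptor, from 41.9 to 65.9 CPM (0.65, adjusted p = 0.0464). Aif1l, an actin-bundling protein, fell (log2 fold change −2.35, adjusted p = 0.0169).

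Of 23 genes of the integrated stress response 0 passed edgeR over all genes (6 at an unadjusted p under 0.05, 1 call each by DESeq2 and limma voom), and adjusted over the list alone 3 fell, Shmt2 (log2 fold change −0.75), Gdf15 and Aldh18a1, and 1 rose, Sesn2. The list was lower in camera (adjusted p = 0.00805), not with the estimated correlation (adjusted p = 0.222 with an estimated correlation), and lower per library (exact permutation test, p = 0.0073, adjusted 0.0344). Of 24 p53 targets 0 passed edgeR (9 at an unadjusted p under 0.05, 1 call by DESeq2 and 0 by limma voom), and adjusted over the list alone 2 fell, Plk2 (−0.75) and Gdf15, and 1 rose (camera adjusted p = 0.000372, adjusted p = 0.247 with an estimated correlation, exact permutation test per library p = 0.0263, adjusted 0.0868). Of 22 heat shock genes 0 passed by either adjustment or another tool (3 at an unadjusted p under 0.05), with −0.71 for Cryab (camera adjusted p = 0.000372, adjusted p = 0.27 with an estimated correlation, exact permutation test per library p = 0.0535, adjusted 0.121). Of 23 glycolysis and hypoxia genes 1 fell by edgeR, P4ha1, for a collagen prolyl hydroxylase (−0.57, adjusted p = 0.0319), by both adjustments. DESeq2 called 1 lower and limma voom 4 lower (camera adjusted p of the list = 0.00038, adjusted p = 0.222 with an estimated correlation). Of 15 inflammatory genes 1 fell by edgeR, Ptgs2, for a prostaglandin synthase (−1.57, adjusted p = 0.0464), and 2 adjusted over the list alone. DESeq2 and limma voom each called 2 lower. That list's median was 0.10, its mean −0.08 and its direction in camera lower (adjusted p = 0.0439, adjusted p = 0.294 with an estimated correlation, and 0.0543 to 0.122 without blebbistatin 4, 5, 6 or 7 or control 5, 6, 7 or 8).

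Of 23 genes that respond to TGF-beta, 1 fell, the transcription factor gene Bhlhe40 (log2 fold change −0.60, adjusted p = 0.0198), while DESeq2 called 2 higher and 3 lower and limma voom 3 lower, and adjusted over the list alone 8 fell and 4 rose. Tgfbi had a log2 fold change of 1.70 (adjusted p = 0.128), and the list did not pass in camera (adjusted p = 0.0868). Settings in which it passed, lower, included limma voom (adjusted p = 0.0153), the covariates for the 10 most abundant genes (0.0218), genes detected (0.0484) and Y-linked genes (0.0109), and the fits without blebbistatin 1 (0.0344), 8 (0.0495) or both (0.0125), while the range was 0.0109 to 0.362 over all alternatives. Of 6 pericyte markers Mcam fell by both adjustments (camera adjusted p = 0.0297, adjusted p = 0.179 with an estimated correlation). This call was also lost with limma voom (adjusted p = 0.167), the covariates for the 10 most abundant genes (0.0843) and macrophage markers (0.0622), and without blebbistatin 1 (0.0949), blebbistatin 2 (0.101), control 4 (0.0597) or blebbistatin 1 and 8 (0.153), and in fry, against no change, the list did not pass (0.0631). Of 24 genes of oxidative phosphorylation encoded in the nucleus 0 passed by either adjustment or another tool (2 at an unadjusted p under 0.05) and 20 were positive (median 0.15, camera adjusted p = 0.0281, adjusted p = 0.294 with an estimated correlation). That call was also lost with the covariate for the 10 most abundant genes (adjusted p = 0.0736), without blebbistatin 1 and 8 (0.14) and, at 0.0528 to 0.118, without blebbistatin 1, 2 or 7 or control 4 or 7, and in fry, against no change, the list did not pass (0.103). Of 24 ribosomal protein genes 0 passed edgeR by either adjustment, with 5 at an unadjusted p under 0.05, 0 calls by DESeq2 and 1 by limma voom (median −0.15, camera adjusted p = 0.00262, adjusted p = 0.345 with an estimated correlation).

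The other lists did not pass in camera. They were targets of the aryl hydrocarbon receptor and NRF2 (15 tested, adjusted p = 0.0635), among which Cyp1a1 had a log2 fold change of 0.99 (adjusted p = 0.0795) and alone rose adjusted over the list alone, interferon response genes (18, adjusted p = 0.069), basement membrane genes (20, adjusted p = 0.285), microtubule genes (20, adjusted p = 0.425), retinoic acid genes (12, adjusted p = 0.679), cholesterol synthesis genes (22, adjusted p = 0.904), endothelial markers (10, adjusted p = 0.714) and neural markers (5, adjusted p = 0.93). Cholesterol genes had a median of 0.02 against a mean of −0.04, endothelial markers a median of 0.13 and a direction lower in camera, and neural markers a median of −0.17 against a mean of 0.29. No member of these lists passed edgeR over all genes, though 1 each of the aryl hydrocarbon receptor, retinoic acid and neural lists passed DESeq2, and 1 each of the aryl hydrocarbon receptor and retinoic acid lists limma voom. In camera the aryl hydrocarbon receptor list passed, higher, without blebbistatin 6 (adjusted p = 0.00783), 7 (0.0364) or control 8 (0.0262), in a range of 0.00783 to 0.331 over all alternatives, and the interferon list, higher, with limma voom (0.0331) and without blebbistatin 5 (0.0404), 8 (0.0495), control 7 (0.0392) or blebbistatin 1 and 8 (0.0452), in a range of 0.0331 to 0.247. At an unadjusted p under 0.05 were 3, 3 and 1 genes of these lists in the same order, 5 of the basement membrane, 6 of the microtubule and 1 of the cholesterol list, and 0 of the interferon and endothelial lists. Adjusted over the list alone Rxra rose (0.49) and Rarg fell (−0.64) among retinoic acid genes, and Ednrb rose (2.63) among neural markers. Erythroid markers, with 2 tested members, and liver markers, with 3, were too few for camera, and 0 of them passed over all genes. Adjusted over the list alone Tfrc fell (−0.85) and Ttr rose (1.75).

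The contractile, SRF and YAP lists share genes. In the 13, 23 and 24 members held by a single list of the 3, the medians were −0.84, −0.36 and −0.32, and each set was lower in camera with an estimated correlation (adjusted p = 0.0155 for each over these 3 tests). Among all 69 genes 59 had a negative log2 fold change, 10 fell and 1 rose.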
